A study of Mus musculus with 18 samples.

How the data were processed

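Total RNA had been labelled with biotin and hybridised to Illumina MouseWG-6 v1.1 BeadArrays, which read each probe as the mean of several beads. The deposited files give, per the file headers, an average signal intensity for each probe on each array, written by BeadStudio, whose version is not given in the sources used here. The intensities are neither background-subtracted nor normalised between arrays, since the array medians differ and no value lies below 0. The deposited files also give, per the file headers, a detection p-value for each probe, which compares its signal with the negative control probes of the same array. The deposited series table holds, per the values, log2 intensities after quantile normalisation without background correction, and it was used as an alternative only. The authors' design text states that the 3 samples per group are biological replicates. The files name no slide, litter or pairing.

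Of 46657 probes, 264 control probes were left out of all tests. The signal was background-corrected from the detection p-values with the normexp method of limma (nec, offset 16) and quantile-normalised on the log2 scale. A probe was tested when its detection p was under 0.05 on at least 3 of the 18 arrays, which kept 21341 probes. One limma model with a term for each of the 6 groups was fitted to all 18 arrays, and each comparison was a contrast of that model with moderated variances. P-values were adjusted by the Benjamini-Hochberg method over the 21341 probes of each comparison, and a probe was called changed at an adjusted p under 0.05. There were 11 contrasts: each model against WT at each age, the later age against the earlier in each genotype, the models against each other at each age, and the interaction of age with each model. Changes are log2 differences between group means with their standard error from limma, and group values are means with their standard deviation over 3 arrays. Software was R 4.3.3, limma 3.58.1, statmod 1.5.0, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

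The files used here do not pair probes with gene symbols. A zero-padded number inside the probe's target identifier was matched to the gene number of the reference table for the mouse build GRCm38.p6, and targets named after RIKEN clones were matched by symbol or synonym. Of 11857 padded numbers, 9796 (82.6%) were gene numbers of the table, against 11.3% of 16393 unpadded numbers, which were left unnamed. The naming was checked against expression: probes so named for olfactory receptors were detected in 4.96% of 343 cases, those for vomeronasal receptors in 1.12% of 89, and those for ribosomal proteins in 92.2% of 77. For 169 pairs of a clone or accession probe and a padded-number probe of the same gene, the median correlation over the arrays was 0.43, against at most 0.21 when the pairs were shuffled. In all 10799 probes for 8695 genes were named, and 5998 of the tested probes (28.1%) for 5177 genes. Counts of changed probes therefore cover all tested probes, whereas gene names, gene lists and chromosomes cover the named ones alone. The 13 mitochondrial probes named in the files carried no gene number, and each such name counted as a gene of its own. Any other gene with several probes was represented by its brightest tested probe. Of 737 such genes, 12 had probes called in opposite directions with age in WT, 6 with age in Ts1Cje and 1 in Ts65Dn against Ts1Cje at 19-20 dpp.

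There were 22 gene lists, fixed before the data were examined, as were the samples of each test, the rule for named genes and the alternatives except where stated. They were the genes in 3 copies in both models on chromosome 16, those in 3 copies in Ts65Dn alone on chromosomes 16 and 17, the genes of the chromosome 12 end affected in Ts1Cje, spermatogonia, meiotic prophase, pachytene to diplotene, round spermatid, Sertoli, Leydig, peritubular, macrophage, endothelial and red cell markers, dissociation stress, p53 and DNA damage, spindle checkpoint, interferon response, oxidative phosphorylation, ribosomal proteins, autosomal retrogenes of sex-linked genes, and sex-linked spermatid genes. The list of genes in 3 copies in Ts65Dn alone on chromosome 16 holds Sod1, since the Ts1Cje translocation carries a disrupted copy of it. Lists were tested against all other tested probes, named or not, with camera of limma at its preset inter-gene correlation of 0.01. They were tested again with the correlation estimated per list. Whole chromosomes were tested against all other tested probes in the same way. The tests of 22 lists in 11 contrasts were adjusted together by the Benjamini-Hochberg method, and so were the tests of whole chromosomes with at least 10 genes in the 11 contrasts. Of all list tests, 41 passed at the preset correlation and 2 with the estimated one, which were the chromosome 17 list in Ts65Dn against WT and against Ts1Cje at 16-17 dpp. The fry test of limma, which asks whether the genes of a list move 1 way on balance without reference to other genes, was computed beside them. Segment means, chromosome X means and an age score per array were compared by exact permutation of the genotype labels within each age, two-sided, with 400 arrangements and a smallest p of 0.005. Within 1 age, 3 arrays against 3 allow no p below 0.1.

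The genes named for a comparison were the 8 largest rises and 8 largest falls among called probes with a symbol and no overlap between the groups, the 4 members with the smallest p of each list, and the 6 with the smallest p of each segment list. Where a probe was undetected on every array of 1 group, the change is given as at least a fold, computed after raising each undetected array to the lowest value at which any probe was detected on that array. The number of arrays limits the precision of every value.

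In a self-test of Ts65Dn against WT at 19-20 dpp, 200 of the 21341 probes were given a known change in each of 20 draws. The changed probes were drawn only from those detected on every array, so recovery of dimmer tested probes was not measured. The spread came from deviations from the group means of all groups, shuffled over the arrays. It was therefore not the spread of the compared groups alone. Recovery was 5.60% at a log2 change of 0.585, the size of 3 copies against 2, 37.8% at 1 and 87.9% at 2, with 1.8 false calls per draw. Of all probes given a change, recovered or not, 98.4% had the right sign. A list raised by 0.585 was found at a median of 0.52. Its unadjusted camera p was under 0.05 in 100% of draws at the preset correlation and in 85% at the estimated one. Calls of lists below rest on adjusted p-values, so these shares do not measure how often such a list would be called there. Unchanged lists had p under 0.05 in 18.8% of cases at the preset correlation and 1.19% at the estimated one.

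The alternatives were no background correction, the deposited series table, median scaling, an offset of 50, no filter, detection at p under 0.01 on all 18 arrays, the mean of a gene's probes, the replicate number as a block, array weights, trend with robust variances, a fit of only the groups compared, and leaving out each array in turn. A block on consecutive run codes of the file headers was added after the data were seen, as were sign flips of the differences between arrays of the same replicate number and age, and the Ts1Cje age score on probes called in Ts65Dn. Whether arrays with the same replicate number behave as pairs was checked by correlating their deviations from the group mean over probes. At 19-20 dpp all 3 numbers had r above 0.1 in each comparison (0.28, 0.22 and 0.18 for Ts65Dn with WT, 0.58, 0.31 and 0.23 for Ts1Cje with WT, 0.57, 0.57 and 0.33 for Ts65Dn with Ts1Cje), and blocked counts stand beside those comparisons. In every other comparison at least 1 number fell below 0.1, the lowest being −0.30.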

Results

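Gene expression was measured in enriched male germ cells of juvenile mice on 18 arrays, 1 per RNA sample. The mice were of 3 genotypes. Ts65Dn is a partial trisomy with an extra marker chromosome that carries distal chromosome 16 and a proximal part of chromosome 17. Ts1Cje is a partial trisomy of a shorter part of distal chromosome 16, carried on chromosome 12, and WT were diploid littermates. The sample labels do not say of which trisomy, and the same WT arrays served for both. Each genotype was sampled at 16-17 and at 19-20 days post partum (dpp), with 3 biological replicates in each of the 6 groups. At these ages the first wave of spermatogenesis passes through meiotic prophase, and the most advanced germ cells go from pachytene spermatocytes towards round spermatids. Between 17102 and 19784 probes were detected per array, and the median signal ranged from 179.4 to 225.2. Of the 22 gene lists, coverage by named and detected probes was partial, for example 20 of 68 genes in 3 copies in both models, 8 of 20 in 3 copies in Ts65Dn alone on chromosome 16, 8 of 31 on chromosome 17, and 2 of 8 of the chromosome 12 end. Every list test below was a camera test at the preset correlation, adjusted over the tests of all lists in all contrasts, unless an estimated correlation is named.

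The change from 16-17 to 19-20 dpp in WT shows what normal progress through meiosis looks like on these arrays. Late germ cell genes rose steeply. Prdm8, a histone methyltransferase family member, rose by 5.24 ± 0.57 (log2, SE, n = 3 and 3, adjusted p = 5.3e-05). Pcdh8, a protocadherin, rose by 5.19 ± 0.49 and Tekt3, a structural protein of sperm flagella, by 5.35 ± 0.82. Prdm8, Pcdh8 and Tekt3 were each detected on 1 of the 3 younger arrays. Of 9 round spermatid genes 6 rose (median 2.37, adjusted p = 0.0015). Among them were Odf2 of the outer dense fibres by 2.62 ± 0.46, the zona-binding Zpbp2 by 3.78 ± 0.75, and Spata20 at least 4.68-fold. Of 7 pachytene to diplotene genes 6 rose (median 1.64, adjusted p = 0.015), including the meiotic kinase Aurkc by 2.16 ± 0.34 and the acrosomal gene Zpbp by 2.75 ± 0.53. Both list calls were lost when the correlation was estimated (adjusted p = 0.70 with an estimated correlation for each). Genes of earlier stages fell while their lists did not pass. Of 7 spermatogonial genes 5 fell (list median −1.01, adjusted p = 0.094), such as the stem cell factor Zbtb16 by −1.06 ± 0.28 and the transcription factor Foxo1 by −1.01 ± 0.25. All 4 meiotic prophase genes fell (list median −0.95, adjusted p = 0.090), such as the cohesin subunits Smc3 by −1.07 ± 0.21 and Smc1a by −1.20 ± 0.27. Adjusted over the list alone, there were again 6, 6, 5 and 4 calls in these 4 lists, in the order given.

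Outside the germ cell lists, the largest named falls in WT were Glrx, a glutaredoxin, by −3.20 ± 1.17, Riox2, a ribosomal oxygenase, at least 4.78-fold, and Acaa1b, a peroxisomal thiolase, by −2.83 ± 0.41, with Chrna4, a nicotinic receptor subunit, at least 2.74-fold lower. Among markers of other testis cells, 4 of 8 Sertoli genes fell (list median −0.94, adjusted p = 0.25), 2 of 10 Leydig genes (−0.40, adjusted p = 0.64) and 1 of 9 peritubular genes (−0.85, adjusted p = 0.18). So did 2 of 4 endothelial genes (−0.90, adjusted p = 0.23), while limma called 0 of 6 macrophage genes (−0.47, adjusted p = 0.88) and 0 of 3 red cell genes (0.39, adjusted p = 0.57). Fallen genes numbered 5 of 7 for dissociation stress (−1.14, adjusted p = 0.15), 3 of 7 for p53 and DNA damage (−0.75, adjusted p = 0.14), 5 of 9 for interferon response (−0.83, adjusted p = 0.15), and 14 of 58 for ribosomal proteins (−0.20, adjusted p = 0.11). Of the latter 1 rose, and 10 fell when adjusted over the list alone. Spindle checkpoint genes were divided, 3 rising and 4 falling (0.18, adjusted p = 0.58), as were oxidative phosphorylation genes, with 2 rising and 7 falling, a median of 0.04 and a mean of −0.08 (adjusted p = 0.91). Among autosomal retrogenes that stand in for sex-linked genes, Taf9, a general transcription factor, rose by 1.12 ± 0.31 (list median 1.12, adjusted p = 0.13). In the sex-linked spermatid list 7 of 9 fell and 1 rose (median −1.13, adjusted p = 0.094), the falls including the Y genes Eif2s3y by −1.26 ± 0.18 and Zfy1 by −1.50 ± 0.28. In all 9964 of 21341 probes changed (46.7%), 3957 up and 6007 down, and the median over all probes was −0.23. The count was 5332 without WT 19-20 dpp replicate 1, 6390 without WT 16-17 dpp replicate 2 and 6275 without WT 16-17 dpp replicate 3.

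Age changes in Ts1Cje were set beside those in WT, since the question was whether germ cells with the shorter trisomy pass the same steps. Prdm8 rose by 5.77 ± 0.57 (log2, SE, n = 3 and 3) and Tekt3 by 5.30 ± 0.82. Of the round spermatid genes 8 of 9 rose (median 2.61, adjusted p = 2.3e-04) and of the pachytene to diplotene genes 6 of 7 (median 2.12, adjusted p = 0.0062). Spermatogonial genes fell in 6 of 7 cases (−1.37, adjusted p = 0.015; 7 adjusted over the list alone), Zbtb16 at least 2.59-fold, and meiotic prophase genes in 4 of 4 (−1.22, adjusted p = 0.028). All 9 peritubular genes fell (−1.79, adjusted p = 0.016), among them smooth muscle actin Acta2 by −2.22 ± 0.54 and the collagen gene Col1a2 at least 3.44-fold. So did 6 of 9 interferon genes (−1.08, adjusted p = 0.038), among them Irf1 by −1.56 ± 0.30, and 22 of 58 ribosomal protein genes (−0.27, adjusted p = 0.021; 16 over the list alone). None of these lists held with an estimated correlation (adjusted p = 0.58 with an estimated correlation for meiotic prophase, 0.70 for each of the others). The peritubular call was also lost without Ts1Cje 16-17 dpp replicate 1 (−1.62, adjusted p = 0.052). So were the interferon and ribosomal calls without Ts1Cje 16-17 dpp replicate 3 (−1.06 and −0.24, adjusted p = 0.053 for both). Osteopontin, Spp1, fell by −3.56 ± 1.05. The fall of Fbxw5, at least 91.8-fold, belongs to a probe with 2 separated levels that occur within single groups. In all 9675 probes changed (45.3%), 3840 up and 5835 down, with a median over all probes of −0.21, and 6429 changed without Ts1Cje 19-20 dpp replicate 1 and 3577 with a fit of only the groups compared. WT and Ts1Cje shared 7479 called probes of the same sign, against 2354 for independent lists, and 2 of opposite sign. By limma the interaction of age with Ts1Cje called 0 probes, with 604 at an unadjusted p under 0.05, and 72 with array weights.

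The age comparison was repeated in Ts65Dn, where Prdm8 rose at least 10.2-fold and Tekt3 by 3.83 ± 0.82 (log2, SE, n = 3 and 3). By limma the interaction of age with Ts65Dn called 0 probes, with 3082 at an unadjusted p under 0.05. That 0 by limma depended on the model and on 2 arrays, with 260 called with the replicate number as a block, 274 with a fit of only the groups compared, 5227 with array weights, 34 without Ts65Dn 19-20 dpp replicate 1 and 1 without WT 16-17 dpp replicate 1. Round spermatid genes rose in 4 of 9 cases (median 0.81, mean 1.29, adjusted p = 0.015), with Odf2 up by 1.87 ± 0.46 and a median of 0.45 (adjusted p = 0.028) without Ts65Dn 19-20 dpp replicate 1. So did pachytene to diplotene genes in 3 of 7 (1.73, adjusted p = 0.014; 5 up and 1 down over the list alone), with Aurkc up by 1.43 ± 0.34. Spermatogonial (−0.39, adjusted p = 0.18) and meiotic prophase genes (−0.47, adjusted p = 0.17) did not pass, as in WT, nor did their interaction of age with Ts65Dn (0.63 and 0.48, adjusted p = 0.14 for both). Leydig cell genes fell (−1.17, adjusted p = 4.8e-04; 4 of 10 called, 8 over the list alone). They included Cyp11a1, which makes the first step of steroid synthesis, at least 10.8-fold, the prolactin receptor Prlr by −3.06 ± 0.69 and the hormone Insl3 by −2.72 ± 0.80. These 3 lists lost their call with an estimated correlation (adjusted p = 0.70, 0.70 and 0.60 with an estimated correlation, in that order). Lpl, a lipase, fell by −3.12 ± 0.75 and C1qb, a complement gene of macrophages, by −2.38 ± 0.64, and 2 of 6 macrophage genes fell (list median −1.20, adjusted p = 0.12). Jak3 fell by −3.68 ± 0.81 on 1 probe, while its other probe differed by 0.33. In all 1857 probes changed (8.70%), 1316 up and 541 down, 1539 of them shared with WT in the same sign and 5 in the opposite sign. Every array moved this count, and so did the model. It was 5413 with the replicate number as a block, 5876 with a fit of only the groups compared, 9430 with array weights, 279 with all probes kept and 1125 with only probes detected on all arrays. It was 29, 10 and 579 without Ts65Dn 16-17 dpp replicates 1, 2 and 3, and 20, 1098 and 50 without Ts65Dn 19-20 dpp replicates 1, 2 and 3. The round spermatid interaction was −0.75 (adjusted p = 0.058), and it passed without WT 16-17 dpp replicate 1 (−1.43, adjusted p = 0.022), WT 19-20 dpp replicates 2 (−0.92, adjusted p = 0.039) or 3 (−0.91, adjusted p = 0.028), Ts65Dn 16-17 dpp replicate 2 (−0.82, adjusted p = 0.0498) or Ts65Dn 19-20 dpp replicate 1 (−1.08, adjusted p = 0.044).

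An age score placed each Ts65Dn and WT array along the age change measured in the third genotype, Ts1Cje. It was the mean of the probes called higher with age in Ts1Cje minus the mean of those called lower. The score therefore adds both directions and is not a mean change per probe. It was 0.00 ± 0.62 (SD, n = 3) in WT and −0.34 ± 0.20 in Ts65Dn at 16-17 dpp, and 2.53 ± 0.39 in WT and 1.06 ± 0.52 in Ts65Dn at 19-20 dpp. At 19-20 dpp Ts65Dn lay lower by −1.47 (exact permutation p = 0.1, the smallest possible), and over both ages by −0.90 (exact permutation p = 0.03; 0.125 by sign flips between arrays of the same replicate number). Ts1Cje, scored on probes called with age in Ts65Dn, differed from WT by −0.21 over both ages (exact permutation p = 0.615). The first principal component held 71.7% of the variance.

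**Figure D1:**
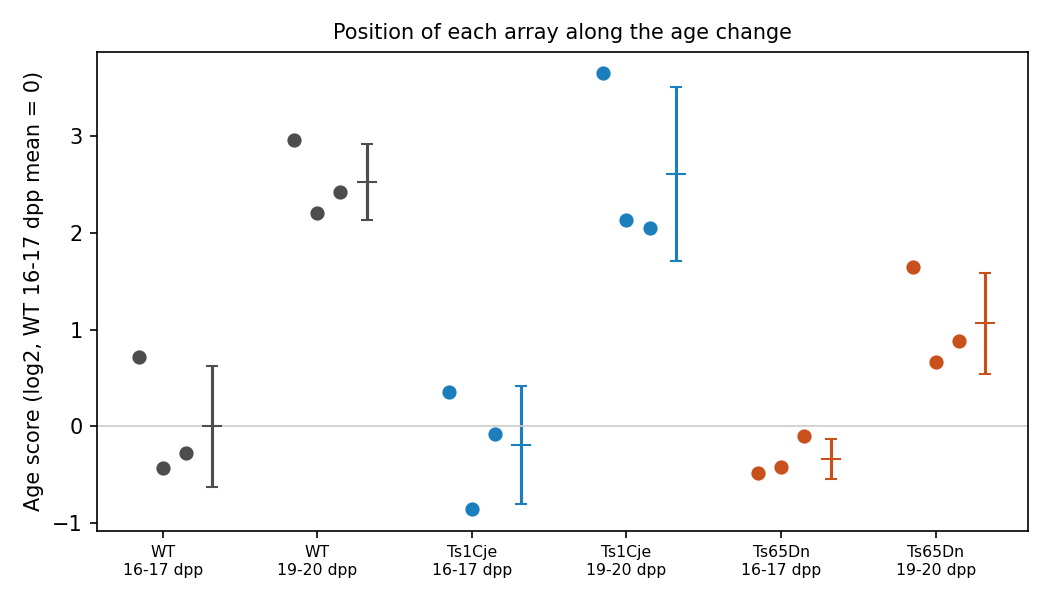
Age score of each array (log2, WT 16-17 dpp mean set to 0) by group. Points are arrays and bars are the mean ± SD of 3, and the Ts65Dn mean at 19-20 dpp (1.06) lies between the WT means of the earlier and the later age, with 1 Ts65Dn array, at 0.66, below the highest younger WT array, at 0.71.

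Ts65Dn was compared with WT at 19-20 dpp to ask which genes differ when meiosis nears its end. Round spermatid genes were lower in Ts65Dn, all 9 below 0 (median −1.39, adjusted p = 0.0066), with Spata20 called at −2.40 ± 0.63 (log2, SE, n = 3 and 3, adjusted p = 0.045). Pachytene to diplotene genes were lower too, 7 of 7 below 0 (−0.66, adjusted p = 0.027), with Aurkc called at −1.31 ± 0.34. The largest named falls were in Fa2h, a fatty acid hydroxylase, from 11.90 ± 0.39 (SD) in WT to 9.15 ± 0.64 in Ts65Dn, in Sptbn4, a spectrin, by −2.64 ± 0.46, and in the testis transcripts 4930483J18Rik by −3.05 ± 0.45 and 4930449I24Rik at least 7.35-fold. Genes of earlier stages were higher. Spermatogonial genes lay above 0 in 7 of 7 cases (median 0.86, adjusted p = 0.028), with 0 called over all probes by limma, 6553 probes being at an unadjusted p under 0.05, and 2 called over the list alone. Meiotic prophase genes lay above 0 in 4 of 4 cases (0.70, adjusted p = 0.043; 1 called over all probes and 4 over the list alone), with Smc3 up by 0.76 ± 0.21. Ribosomal protein genes were slightly higher, 50 of 58 above 0 (0.20, adjusted p = 0.025), with Rpl10a up by 0.73 ± 0.19. With an estimated correlation no call held (adjusted p = 0.60 with an estimated correlation for meiotic prophase, 0.70 for each of the others). Acaa1b rose by 1.96 ± 0.41, Eng, an endothelial TGF-beta co-receptor, by 1.43 ± 0.34, and Rtn2, a reticulon, by 1.30 ± 0.26. The Y genes Eif2s3y, Usp9y and Rbmy rose by 1.03 ± 0.18, 0.92 ± 0.18 and 0.73 ± 0.19 (sex-linked spermatid list median 0.82, mean 0.23, adjusted p = 0.064). The spermatogonial call was lost without WT replicate 3 (0.81, adjusted p = 0.055) and the meiotic prophase call without WT replicate 2 (0.76, adjusted p = 0.080) or Ts65Dn replicate 3 (0.64, adjusted p = 0.051). The ribosomal call was lost without WT replicate 1 (0.14, adjusted p = 0.066) or Ts65Dn replicate 1 (0.18, adjusted p = 0.097), and the sex-linked list was called without WT replicate 1 (0.65, adjusted p = 0.034) or Ts65Dn replicate 2 (0.78, adjusted p = 0.043).

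Lists of other cell types did not pass in Ts65Dn against WT at 19-20 dpp. Their medians were 0.22 for Sertoli, −0.14 for Leydig, 0.38 for peritubular, −0.90 for macrophage, 0.64 for endothelial and −0.39 for red cell genes (adjusted p = 0.36, 0.84, 0.77, 0.12, 0.13 and 0.59). Stress and repair lists lay above 0 without passing, at 0.43 for dissociation stress, 0.54 for p53 and DNA damage and 0.46 for interferon response (adjusted p = 0.13, 0.13 and 0.14). Retrogenes (−0.34, adjusted p = 0.35), spindle checkpoint (−0.20, adjusted p = 0.41) and oxidative phosphorylation genes (0.11, adjusted p = 0.64; −0.05 with median scaling) did not pass. Altogether 1028 of 21341 probes changed, 384 up and 644 down, and 117 named genes rose while 118 fell. The median over all probes was 0.11, and 0.03 with median scaling. Of the 1028, 1020 (99.2%) moved against the age change measured in Ts1Cje, and over all probes the correlation of the 2 changes was −0.87, where probes are not independent replicates. The probes called with age in Ts1Cje had a median change in the age direction of 0.94 in WT and 0.45 in Ts65Dn. Single arrays moved the count, to 1, 565 and 104 without WT replicates 1, 2 and 3 and to 2021, 0 and 0 by limma without Ts65Dn replicates 1, 2 and 3. It was 5074 with the replicate number as a block and 10474 with array weights, and the share that rose went from 37.4% to 54.6% and 57.6% with these. With only probes detected on all arrays 551 changed, 56.1% of them up.

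At 16-17 dpp the same comparison asks whether Ts65Dn germ cells already differ in mid prophase. Tor1aip2, which regulates a torsin ATPase of the endoplasmic reticulum, rose at least 2.37-fold (n = 3 and 3, adjusted p = 0.024) and was the only named gene called. Leydig cell genes were higher, 10 of 10 above 0 (median 0.91, adjusted p = 2.6e-05; adjusted p = 0.58 with an estimated correlation), with 0 called over all probes by limma and 2 over the list alone. Their values included at least 1.41-fold for Hsd11b1, a glucocorticoid enzyme, at least 1.42-fold for the luteinising hormone receptor Lhcgr, detected on 2 of the 3 Ts65Dn arrays, and 1.92 ± 0.86 (log2, SE) for Cyp11a1. Round spermatid (−0.30, adjusted p = 0.35), pachytene to diplotene (−0.76, adjusted p = 0.094), spermatogonial (0.23, adjusted p = 0.23) and meiotic prophase genes (0.19, adjusted p = 0.30) did not pass. The pachytene to diplotene list was called without WT replicate 2 (−0.92, adjusted p = 0.027). In all 4 probes rose and 0 fell by limma, with 1655 at an unadjusted p under 0.05. The 4 became 15 with the replicate number as a block, 24 with a fit of only the groups compared and 488 with array weights. They became 1, 1 and 0 without WT replicates 1, 2 and 3 and 8, 0 and 0 without Ts65Dn replicates 1, 2 and 3. None of the 4 probes was called at 19-20 dpp, where Tor1aip2 differed by 0.03 ± 0.28 (log2, SE, adjusted p = 0.95).

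Genes carried in 3 copies were examined as groups, to see how far the extra copies show in RNA, where 3 copies against 2 would give 0.585. In Ts65Dn at 16-17 dpp the 20 measured chromosome 16 genes shared by both models were higher by a median of 0.58 (18 above 0, adjusted p = 6.9e-10), the 8 present in 3 copies in Ts65Dn alone by 0.66 (8 above 0, adjusted p = 1.9e-05), and the 8 on chromosome 17 by 0.59 (7 above 0, adjusted p = 1.4e-06). With an estimated correlation chromosome 17 held (adjusted p = 0.011) and the others did not (adjusted p = 0.48 and 0.43 with an estimated correlation). By limma 0 of these genes passed over all probes, whereas 5, 4 and 7 passed when adjusted over the list alone. Values included 0.88 ± 0.19 (log2, SE, n = 3 and 3) for the kinase Dyrk1a, 1.43 ± 0.41 for the junction protein Jam2, 0.73 ± 0.25 for the amyloid precursor App, and 0.80 ± 0.22 for the membrane linker Ezr on chromosome 17. At 19-20 dpp in Ts65Dn, App rose from 12.16 ± 0.36 (SD) to 13.55 ± 0.23, the superoxide dismutase Sod1 by 1.08 ± 0.18, the transcription factor Gabpa by 1.00 ± 0.19 and the repressor Bach1 by 1.23 ± 0.26. These 4 of the 8 were called, 5 over the list alone (median 1.04, adjusted p = 0.0044; adjusted p = 0.58 with an estimated correlation). The mean of these 8 genes fell with age on WT arrays, being 9.99 to 10.26 at 16-17 dpp and 9.35 to 9.61 at 19-20 dpp. Ts65Dn had the lower age score at 19-20 dpp (1.06 against 2.53 in WT). How much of the rise at that age came from the extra copies therefore cannot be told. Among the 20 shared genes, Ttc3, a ubiquitin ligase, rose by 1.05 ± 0.22 while Mx2, an antiviral GTPase, fell by −0.90 ± 0.23, with 9 up and 1 down over the list alone (median 0.58, mean 0.46, 14 above 0, adjusted p = 0.086). The shared list passed without WT 19-20 dpp replicate 1 (0.54, adjusted p = 0.037) and with the replicate number as a block (0.58, adjusted p = 0.047). On chromosome 17 the palmitoyltransferase Zdhhc14 rose by 1.02 ± 0.26, with 4 of 8 over the list alone (0.42, adjusted p = 0.18). Over both ages the segment means were higher in Ts65Dn by 0.52, 0.77 and 0.50 for the shared, Ts65Dn-alone and chromosome 17 genes (exact permutation p = 0.005 each, the smallest possible; 0.013 after Benjamini-Hochberg adjustment over 8 tests). Between arrays of the same replicate number and age, all 6 differences lay above 0 for each segment (exact permutation p by sign flips = 0.0313, the smallest possible; 0.0625 after the same adjustment). The 2 chromosome 12 genes, not in 3 copies in Ts65Dn, differed there by 0.38 over both ages (exact permutation p = 0.16). Their difference was 0.04 at 16-17 dpp and 0.72 at 19-20 dpp (exact permutation p = 0.2 for the latter).

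**Figure D2:**
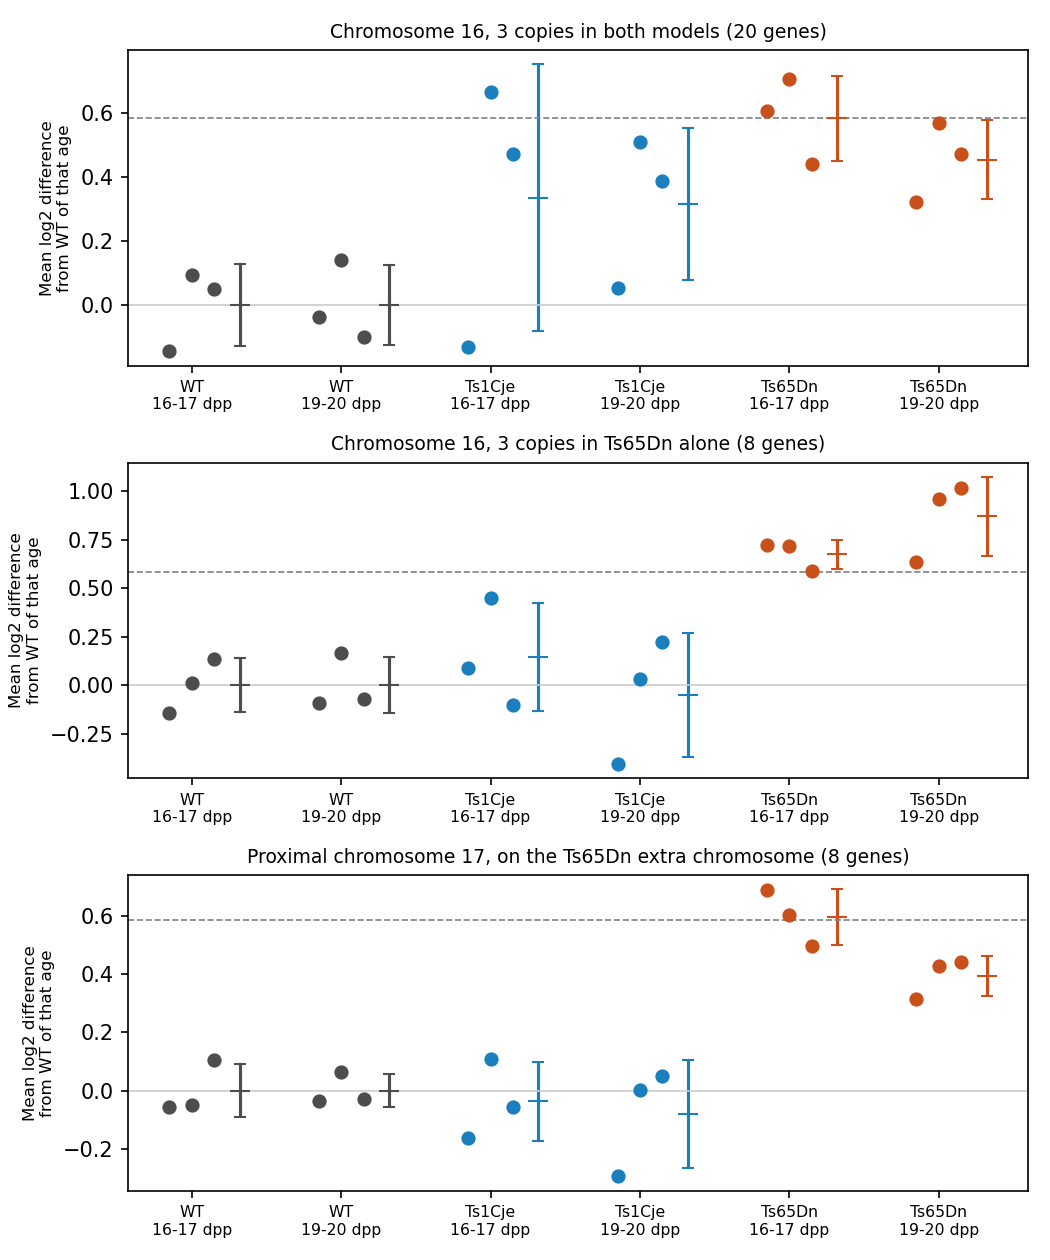
Mean log2 difference of each array from the WT mean of its age, for 20 chromosome 16 genes in 3 copies in both models, 8 in 3 copies in Ts65Dn alone and 8 on chromosome 17. Points are arrays, bars are the mean ± SD of 3, the dashed line is the log2 of 3 copies over 2 (0.585), and in the shared panel the array labelled Ts1Cje 16-17 dpp replicate 1 lies at −0.13.

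Ts1Cje was compared with WT to ask what the shorter trisomy changes. The shared chromosome 16 genes were higher by a median of 0.35 at 16-17 dpp (18 of 20 above 0, adjusted p = 2.5e-09) and of 0.33 at 19-20 dpp (19 of 20 above 0, adjusted p = 5.4e-08). These calls were lost with an estimated correlation (adjusted p = 0.48 and 0.57 with an estimated correlation). Dyrk1a differed by 0.66 ± 0.19 and 0.51 ± 0.19 (log2, SE, n = 3 and 3) at the earlier and later age. Psmg1, a proteasome assembly factor, differed by 0.46 ± 0.15 at 16-17 dpp, and Eva1c, a membrane receptor, by 0.45 ± 0.15 at 19-20 dpp. Sod1, disrupted on the translocated segment, differed by 0.05 ± 0.18 and 0.14 ± 0.18. Over both ages the shared mean was higher by 0.33 (exact permutation p = 0.055; 0.11 after Benjamini-Hochberg adjustment over 8 tests). This permutation ignores the replicate number. Between arrays of the same number and age, all 6 differences lay above 0, from 0.01 to 0.58 (exact permutation p by sign flips = 0.0313, the smallest possible; 0.0625 after the same adjustment). The array labelled Ts1Cje 16-17 dpp replicate 1 lay at −0.13 against the WT mean, and the other arrays of its group at 0.67 and 0.47. At 19-20 dpp the Ts1Cje arrays lay at 0.05, 0.51 and 0.39 (replicates 1, 2 and 3). Without it the median at 16-17 dpp was 0.62, a value to be read with care, since the array stands out by the same genes, though it also lacked the neomycin signal described below. Genes in 3 copies in Ts65Dn alone differed in Ts1Cje by 0.05 over both ages (exact permutation p = 0.73), those on chromosome 17 by −0.06 (exact permutation p = 0.455), and the 2 genes of the chromosome 12 end by 0.02 (exact permutation p = 0.925). Published maps of the strain put genes at this end of chromosome 12 at 1 copy. Whether the 2 measured genes are among those was not checked here. They are also too few, and without a shared fall, so that they do not test the loss of a copy. At 19-20 dpp those 2 moved apart, Cdca7l at −0.71 ± 0.27 and Rapgef5 at 0.72 ± 0.30, and both passed when adjusted over the list alone.

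Outside the segments, peritubular genes were lower in Ts1Cje at 19-20 dpp, 0 of 9 above 0 (−0.52, adjusted p = 0.0067; adjusted p = 0.70 with an estimated correlation), with Col1a2 at least 1.34-fold lower. Leydig genes were higher, 9 of 10 above 0 (0.43, adjusted p = 0.016; adjusted p = 0.70 with an estimated correlation). At 16-17 dpp red cell genes were higher, 3 of 3 above 0 (0.51, adjusted p = 0.016; adjusted p = 0.48 with an estimated correlation), with the globin Hba-a1 at 1.15 ± 0.44 (log2, SE, n = 3 and 3), and so were ribosomal protein genes, 39 of 58 above 0 (0.04, adjusted p = 0.0498; adjusted p = 0.75 with an estimated correlation). These calls, with 0 members called over all probes or over the list alone by limma, depended on single arrays. The peritubular call was lost without WT replicates 1 (−0.19, adjusted p = 0.31) or 2 (−0.50, adjusted p = 0.078) or Ts1Cje replicate 1 (−0.23, adjusted p = 0.55) of 19-20 dpp. The Leydig call was lost without WT replicate 3 (0.35, adjusted p = 0.11), Ts1Cje replicate 2 (0.16, adjusted p = 0.20) or Ts1Cje replicate 3 (0.15, adjusted p = 0.32). The red cell call was lost without WT replicates 2 (0.56, adjusted p = 0.097) or 3 (0.62, adjusted p = 0.057) or Ts1Cje replicates 1 (0.79, adjusted p = 0.082) or 3 (0.70, adjusted p = 0.086) of 16-17 dpp. The ribosomal call was lost at that age without WT replicates 1 (0.01, adjusted p = 0.66) or 2 (0.06, adjusted p = 0.062) or Ts1Cje replicates 1 (0.03, adjusted p = 0.10) or 3 (0.03, adjusted p = 0.38). Without Ts1Cje 16-17 dpp replicate 1, spermatogonial (0.41, adjusted p = 0.016) and Leydig genes (0.68, adjusted p = 0.0065) were called higher and pachytene to diplotene genes lower (−0.62, adjusted p = 0.039). Other lists were called only without 1 array. At 19-20 dpp round spermatid genes (0.41, adjusted p = 0.17) were called higher without WT replicate 1 (0.75, adjusted p = 0.0050) or Ts1Cje replicates 2 (0.72, adjusted p = 0.017) or 3 (0.92, adjusted p = 0.0037). Spermatogonial genes (−0.23, adjusted p = 0.15) were called lower without Ts1Cje replicate 3 (−0.32, adjusted p = 0.029), and Sertoli genes (0.32, adjusted p = 0.11) higher without Ts1Cje replicate 1 (0.78, adjusted p = 0.0067). At 16-17 dpp lists called higher were spermatogonial genes without WT replicate 3 (0.23, adjusted p = 0.040) and peritubular genes without WT replicate 2 (0.80, adjusted p = 0.0033) or Ts1Cje replicate 3 (0.49, adjusted p = 0.029). Macrophage (0.75, adjusted p = 0.011) and oxidative phosphorylation genes (0.10, adjusted p = 0.030) were called without Ts1Cje replicate 2. No single probe passed: limma called 0 at each age, with 427 at 16-17 dpp and 633 at 19-20 dpp at an unadjusted p under 0.05. At 19-20 dpp 3 were called without WT replicate 3, 7 without Ts1Cje replicate 1 and 3 without Ts1Cje replicate 2, and 0 with the replicate number as a block. With array weights 34 and 32 were called at the earlier and later age.

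The trisomies were also compared with each other, which separates the genes in 3 copies in Ts65Dn alone from those in 3 copies in both. At 16-17 dpp Ts65Dn was higher than Ts1Cje by a median of 0.50 on the Ts65Dn-alone genes of chromosome 16 (adjusted p = 8.5e-05; adjusted p = 0.48 with an estimated correlation) and of 0.55 on chromosome 17 (adjusted p = 2.5e-09; adjusted p = 0.0042 with an estimated correlation). Values included Ezr at 1.06 ± 0.22 (log2, SE, n = 3 and 3) and App at 0.88 ± 0.25. Over the list alone 4 of 8 and 6 of 8 passed. The shared genes differed by 0.24 (adjusted p = 0.025; adjusted p = 0.70 with an estimated correlation), a call lost without the array labelled Ts1Cje 16-17 dpp replicate 1 (−0.03, adjusted p = 0.96), Ts65Dn replicate 1 (0.18, adjusted p = 0.052) or Ts65Dn replicate 2 (0.16, adjusted p = 0.11). Leydig genes were higher in Ts65Dn (0.62, adjusted p = 6.3e-04; adjusted p = 0.62 with an estimated correlation; 0.37, adjusted p = 0.039 without Ts1Cje replicate 1) and spindle checkpoint genes lower (−0.16, adjusted p = 0.038; adjusted p = 0.57 with an estimated correlation). The spindle call was lost without Ts1Cje replicates 1 (−0.15, adjusted p = 0.052), 2 (−0.16, adjusted p = 0.078) or 3 (−0.20, adjusted p = 0.087) or Ts65Dn replicate 3 (−0.09, adjusted p = 0.12). Pachytene to diplotene genes (−0.33, adjusted p = 0.17) were called without Ts1Cje replicate 2 (−1.07, adjusted p = 0.0056). By limma 0 probes changed at 16-17 dpp, with 1084 at an unadjusted p under 0.05, and 1 changed without Ts1Cje replicate 3 or Ts65Dn replicate 3, 6 with a fit of only the groups compared and 122 with array weights.

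At 19-20 dpp Sod1 (0.94 ± 0.18, log2, SE, n = 3 and 3), App (1.26 ± 0.25) and Gabpa (1.11 ± 0.19) were higher in Ts65Dn than in Ts1Cje. Of the 8 Ts65Dn-alone genes 5 rose (median 1.02, adjusted p = 0.0062; 6 up and 1 down over the list alone), while the shared genes differed by 0.04 (adjusted p = 0.86; −0.05 with median scaling). The mean of the 8 Ts65Dn-alone genes fell with age on Ts1Cje arrays, being 10.03 to 10.58 at 16-17 dpp and 9.04 to 9.66 at 19-20 dpp. Copy number and the lower age score of Ts65Dn were therefore not told apart in their rise. On chromosome 17, 3 of 8 rose, among them Scaf8 by 1.19 ± 0.24 and Ezr by 0.77 ± 0.22 (0.48, adjusted p = 0.13). Round spermatid genes were lower (−1.33, adjusted p = 0.0011), Spata20 by −3.06 ± 0.63 and the sperm kinase Tssk1 by −1.91 ± 0.50. Pachytene to diplotene genes were lower (−0.72, adjusted p = 0.019), and spermatogonial (0.87, 5 of 7 called, adjusted p = 0.0067), meiotic prophase (0.76, 2 of 4 called, adjusted p = 0.028) and ribosomal protein genes (0.18, 6 up and 1 down, adjusted p = 0.016) higher. None of these 6 lists held with an estimated correlation (adjusted p = 0.58 with an estimated correlation for the Ts65Dn-alone and meiotic prophase genes, 0.67 for spermatogonia, 0.70 for the others). Other large rises were Spp1 by 3.82 ± 1.05, Ltbp2 by 2.83 ± 0.59, elastin (Eln) by 2.06 ± 0.54 and Acta2 by 2.08 ± 0.54, beside a peritubular list of 0.92 (2 of 9 called, adjusted p = 0.14). The fall of Rpl29 by −3.90 ± 1.09 belongs to a probe with 2 separated levels. In all 2501 probes changed, 1557 up and 944 down, with a median over all probes of 0.09, which median scaling shifted by −0.10. The count was 5460 with the replicate number as a block, 3 with a fit of only the groups compared, 7149 with array weights, 380 without Ts1Cje replicate 1, and 95 and 195 without Ts65Dn replicates 2 and 3. Calls that single arrays decided were the pachytene to diplotene list, lost without Ts1Cje replicate 1 (−0.54, adjusted p = 0.074), and the ribosomal list, lost without Ts65Dn replicate 1 (0.18, adjusted p = 0.060). Leydig (−0.59, adjusted p = 0.0027), macrophage (−1.28, adjusted p = 0.0010) and sex-linked spermatid genes (0.58, adjusted p = 0.036) were called without Ts1Cje replicate 1, and endothelial genes without Ts1Cje replicate 3 (1.09, adjusted p = 0.044). Macrophage (−1.04, adjusted p = 0.030) and endothelial genes (0.96, adjusted p = 0.037) were also called without Ts65Dn replicate 2.

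Chromosome X genes were followed because the sex chromosomes are silenced in pachytene spermatocytes. Their medians are relative to all other named genes, whereas the adjusted p compares X genes with all other tested probes. Relative to all other genes, the 169 measured X genes fell with age by a median of −0.71 in WT (114 down, 3 up, adjusted p = 1.1e-08), −0.71 in Ts1Cje (104 down, 2 up, adjusted p = 8.4e-09) and −0.45 in Ts65Dn (7 down, 0 up by limma, adjusted p = 1.7e-09). In Ts65Dn they lay above WT by 0.19 at 16-17 dpp (adjusted p = 2.1e-04) and by 0.42 at 19-20 dpp (12 up, adjusted p = 5.2e-07). Mbtps2, a membrane protease, rose there by 1.27 ± 0.30 (log2, SE, n = 3 and 3; detected on 1 of 3 WT arrays) and the kinase Rps6ka3 by 1.24 ± 0.29. They also lay above Ts1Cje, by 0.17 at 16-17 dpp (adjusted p = 0.0086) and by 0.38 with 30 up at 19-20 dpp. Every X call was lost with an estimated correlation (adjusted p = 0.93 with an estimated correlation). As array means, X minus other genes was −0.41 ± 0.19 (SD, n = 3) in WT, −0.39 ± 0.19 in Ts1Cje and −0.24 ± 0.11 in Ts65Dn at 16-17 dpp, and −1.14 ± 0.09, −1.11 ± 0.39 and −0.74 ± 0.21 at 19-20 dpp. At single ages Ts65Dn differed from WT in these means by 0.17 and 0.40 (exact permutation p = 0.3 and 0.1, with 0.1 the smallest possible). Over both ages Ts65Dn differed from WT by 0.29 (exact permutation p = 0.015; 0.0625 by sign flips between arrays of the same replicate number) and Ts1Cje by 0.03 (exact permutation p = 0.855), and the interaction of age with Ts65Dn did not pass (0.23, adjusted p = 0.070). In each group the array with the highest age score had the lowest X value, such as −1.56 at a score of 3.65 for Ts1Cje 19-20 dpp replicate 1. The score itself includes X genes called with age. The X difference of Ts65Dn from WT was therefore not told apart from its lower age score (1.06 against 2.53 at 19-20 dpp). The X rise of Ts65Dn at 16-17 dpp against WT was lost without WT 16-17 dpp replicate 1 (0.09, adjusted p = 0.50). The fall in Ts1Cje was −0.42 and the later rise against Ts1Cje 0.16 without Ts1Cje 19-20 dpp replicate 1, and the latter was 0.61 without Ts1Cje 19-20 dpp replicate 3. Mitochondrial genes, with 2 of 20 called, were the other chromosome group called by camera in Ts65Dn against WT at 19-20 dpp. Their value was 0.28 (adjusted p = 0.0086, and adjusted p = 0.93 with an estimated correlation). A mitochondrial gene may be counted more than once among the 20, since those named in the files were not merged with probes named by number.

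**Figure D3:**
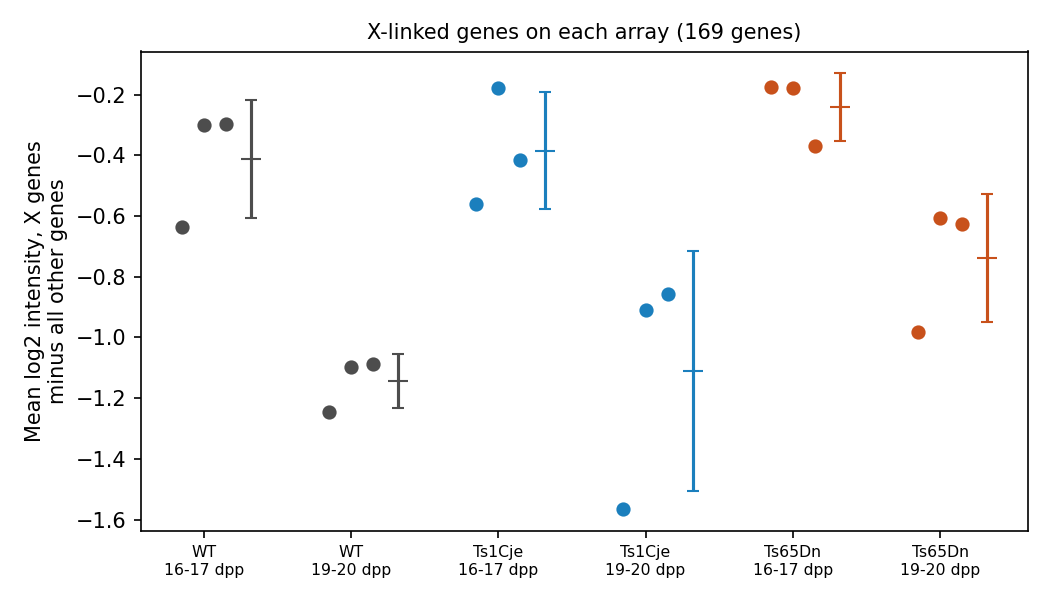
Mean log2 intensity of 169 chromosome X genes minus that of all other genes, per array and group. Points are arrays and bars are the mean ± SD of 3, and the values at 19-20 dpp average −1.14 in WT, −1.11 in Ts1Cje and −0.74 in Ts65Dn.

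A control probe for the neomycin resistance gene marked 5 of the 18 arrays. The Ts1Cje translocation arose in cells with a neomycin cassette in Sod1, which the other mice lack. The probe read 9.27 to 10.78 (log2) and was detected on 5 of the 6 Ts1Cje arrays, and read 5.54 to 5.80, undetected, on the other 13 arrays. The array labelled Ts1Cje 16-17 dpp replicate 1 was among those 13, at 5.65 with a detection p of 0.508.

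**Figure D4:**
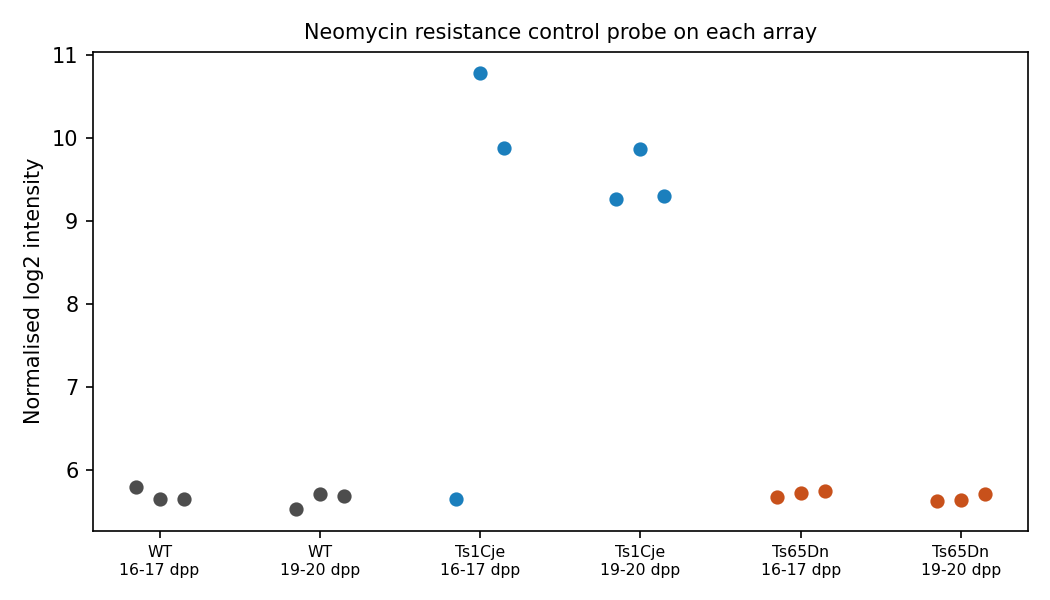
Normalised log2 intensity of the neomycin resistance control probe on each array, by group. Points are arrays, and 1 array of the Ts1Cje 16-17 dpp group lies at the level of the WT and Ts65Dn arrays.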

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

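The tests of the 3 patterns below were chosen after the patterns had been seen, whereas the counts under other splits of the arrays were planned before.

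The neomycin resistance probe, a control probe that the comparisons did not use, carried a signal of up to 10.78 (log2) on Ts1Cje arrays, above 5.80, its highest level on the arrays of the other genotypes. Peritubular genes changed with age differently in Ts1Cje and WT, with an interaction of −0.80 (adjusted p = 0.0062; adjusted p = 0.70 with an estimated correlation), which was lost without WT 16-17 dpp replicate 1 (−0.50, adjusted p = 0.15), WT 19-20 dpp replicate 1 (−0.51, adjusted p = 0.12), Ts1Cje 16-17 dpp replicate 1 (−0.64, adjusted p = 0.053) or Ts1Cje 19-20 dpp replicate 1 (−0.55, adjusted p = 0.23). Leydig genes changed with age differently in Ts65Dn and WT, with a median interaction of −0.69 and a mean of −1.16 (adjusted p = 0.011; adjusted p = 0.70 with an estimated correlation). Mitochondrial genes, some of which may be counted more than once, did so too by camera. Their interaction was 0.39 (adjusted p = 0.0050, and adjusted p = 0.93 with an estimated correlation).

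The array labelled Ts1Cje 16-17 dpp replicate 1 lacked the neomycin signal. A single wrong label or a diploid animal would put its shared chromosome 16 genes within the WT range, and they lay at −0.13 from the WT mean of that age. This alone does not decide. Ts1Cje 19-20 dpp replicate 1 carried the signal, at 9.27, and lay at 0.05, within the WT range of its age (−0.10 to 0.14). That array was lower still on the Ts65Dn-alone genes (−0.41) and on the chromosome 17 list (−0.29), so its shared genes lay above both. Ts1Cje 16-17 dpp replicate 1 lay at 0.09 and −0.16 on these lists, and its shared genes were not above both. Shared genes above both lists do not mark the trisomy either, since WT 16-17 dpp replicate 2 had them (0.09 against 0.01 and −0.05). A dim array would show fewer detected probes than the arrays with the signal. Ts1Cje 16-17 dpp replicate 1 had 18570, against 17102 to 19161 on those. A swap with a WT array would leave the signal on a WT array, but 0 WT arrays carried it. These last 2 values argue against a dim array and a swap, and a wrong label or a diploid animal stays open.

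On average Ts65Dn at 19-20 dpp lay between the earlier and the later age of WT. More cells of all other types in the Ts65Dn samples would raise all 5 somatic lists. The lowest, macrophage genes, had a mean of −0.74 ± 0.24 (SE over genes), while endothelial genes had 0.74 ± 0.25 and Sertoli genes 0.35 ± 0.13. That argues against a joint rise of all 5 types, over genes and not over arrays. An excess of some of these types stays open. Dimmer Ts65Dn arrays would detect fewer probes than every WT array of that age, and 0 of 3 did. Slower progress of Ts65Dn germ cells, or younger mice within the stated window, would move changed probes against the age change of another genotype. Of the changed probes 99.2% moved so. That share restates the position between the WT ages, and any other cause of that position would give it too. It therefore tests neither explanation. Slower progress and younger mice cannot be told apart here, since each mouse's exact age is not given in the sources used here.

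Probes with 2 separated levels across the 18 arrays numbered 54, with a gap over 2 (log2) and at least 3 arrays on each side. Genotype or age of the groups would put each group wholly on 1 level, but 39 of the 54 had both levels inside a group, which argues against it for most of them. A variant carried by some animals, or a fault of single arrays, would split arrays the same way at several probes, and the largest set of the 39 doing so held 5, which cannot tell these apart. Of the 4 probes that rose in Ts65Dn at 16-17 dpp, 2 were of this kind. For 1 of those 2, unnamed, the 3 WT arrays of that age were low, and all 3 arrays of each trisomy were high.

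Other splits of the same arrays were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Ts65Dn against WT changed 1028 probes at 19-20 dpp and 4 at 16-17 dpp, and the highest other split changed 0 at each age, so that 1 split, the real one, reached the count. With age, 9964 probes changed in WT, 9675 in Ts1Cje and 1857 in Ts65Dn, and the highest other splits changed 1, 1 and 2. Ts65Dn against Ts1Cje changed 2501 at 19-20 dpp, with 0 in the highest other split, and 0 at 16-17 dpp, which all 10 splits reached. Ts1Cje against WT changed 0 at each age, reached by all 10 splits, of which the highest others changed 769 at 16-17 dpp and 540 at 19-20 dpp. For the interactions 100 splits were drawn, and all 100 reached the real count of 0, the highest changing 4198 for Ts1Cje and 1 for Ts65Dn. In Ts1Cje against WT the high counts, 769 at 16-17 dpp and 540 and 81 at 19-20 dpp, came from splits that parted only 1 of the 3 pairs of arrays sharing a replicate number, and splits that parted all 3 pairs changed at most 1. The split with 769 set apart WT replicate 1 and Ts1Cje replicates 1 and 3. On the age score from probes called in Ts65Dn these were the highest at 16-17 dpp (0.93, 0.87 and −0.15, against −0.44 or lower). Both high splits at 19-20 dpp kept together WT and Ts1Cje replicate 1, the highest of that age (3.48 and 3.74). The high counts thus go with position along the age change as well as with the replicate number, and these were not told apart.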

How the results depend on the processing

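Of 18528 values of named genes under an alternative, 16902 kept their direction and their side of the threshold, 779 became weaker, 551 stronger, 296 moved and 0 reversed. Trend with robust variances changed no main result. Unless a cause is given, the cause was not tested. Below, the counts are of changed probes in the order Ts1Cje against WT, Ts65Dn against WT, age in WT, Ts1Cje and Ts65Dn, Ts65Dn against Ts1Cje, and interactions.

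Without a filter the counts were 1 for Ts1Cje at 19-20 dpp, 0 (limma) and 383 for Ts65Dn at 16-17 and 19-20 dpp, 279 for age in Ts65Dn, 1372 for Ts65Dn against Ts1Cje at 19-20 dpp and 1 for each interaction, and the shared chromosome 16 genes passed in Ts65Dn at 19-20 dpp at 0.11 (adjusted p = 0.0091), where undetected genes join the list. With detection at p under 0.01 on all 18 arrays, which leaves fewer probes and list members, the counts were 1 for Ts1Cje and 1 for Ts65Dn at 16-17 dpp, 551 for Ts65Dn at 19-20 dpp, 5889, 5182 and 1125 with age, and 1365 for Ts65Dn against Ts1Cje at 19-20 dpp. There, 23 fixed lists passed in place of 41. The shared genes in Ts65Dn at 19-20 dpp became stronger (0.71, adjusted p = 0.033), the Ts65Dn-alone genes weaker (1.04, adjusted p = 0.056; −0.023 and 0.14 in Ts1Cje), and the chromosome 12 list, then a single gene, stood at −0.32 at 16-17 dpp and reversed to −0.71 (adjusted p = 0.045) at 19-20 dpp.

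With the replicate number as a block the counts were 1 for Ts1Cje at 16-17 dpp, 15 and 5074 for Ts65Dn, 5413 for age in Ts65Dn, 5460 for Ts65Dn against Ts1Cje at 19-20 dpp, and 1 and 260 for the interactions, and the shared genes passed in Ts65Dn at 19-20 dpp (0.58, adjusted p = 0.047). A block on the slide was not run, since the files name no slide. The run code block, chosen after the data were seen, gave 2748 for Ts65Dn at 19-20 dpp, 3859 for age in Ts65Dn and 3881 for Ts65Dn against Ts1Cje at 19-20 dpp.

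Array weights gave 34 and 32 for Ts1Cje at 16-17 and 19-20 dpp, 488 and 10474 for Ts65Dn, 9430 for age in Ts65Dn, 122 and 7149 for Ts65Dn against Ts1Cje, and 72 and 5227 for the interactions, with −0.12 and 0.078 for the Ts65Dn-alone genes in Ts1Cje and −0.12 for chromosome 12 at 16-17 dpp. A fit of only the groups compared gave 5 and 1 for Ts1Cje, 24 for Ts65Dn at 16-17 dpp, 3577 and 5876 for age in Ts1Cje and Ts65Dn, 6 and 3 for Ts65Dn against Ts1Cje and 274 for the Ts65Dn interaction. The chromosome 12 list of 2 genes in Ts1Cje moved to −0.055 and −0.15 without background correction, to −0.055 and −0.15 with the series table, to −0.014 at 19-20 dpp with median scaling, to −0.0040 and −0.070 with an offset of 50, and to −0.069 and −0.20 with the mean of a gene's probes. The share of risen probes in Ts65Dn against WT at 19-20 dpp was 37.4%, against 54.6% with the block, 56.1% with the strict filter and 57.6% with weights.

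Leaving out 1 array at a time, the counts ranged from 0 to 7 for Ts1Cje at 19-20 dpp, from 0 to 8 and from 0 to 2021 for Ts65Dn at 16-17 and 19-20 dpp, from 5332 to 10356, from 6429 to 10435 and from 10 to 1098 with age in WT, Ts1Cje and Ts65Dn, from 0 to 1 and from 95 to 3678 for Ts65Dn against Ts1Cje, and from 0 to 1 and from 0 to 34 for the Ts1Cje and Ts65Dn interactions. The chromosome 12 list ranged from −0.27 to 0.29 at 16-17 dpp and from −0.10 to 0.12 at 19-20 dpp, the Ts65Dn-alone genes in Ts1Cje from −0.049 to 0.15 and from −0.17 to 0.077, the shared genes in Ts65Dn at 19-20 dpp from 0.38 to 0.68, and X genes in Ts65Dn against WT at 16-17 dpp from 0.088 to 0.26. Signal close to background limits what can be seen of dim genes, whose values the offset and the filter set.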

Other observations

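The class I histocompatibility gene H2-D1 on chromosome 17, outside the Ts65Dn segment list, showed values that the comparisons with WT did not call. At 16-17 dpp it was detected on 0 of 3 WT arrays and on 3 of 3 arrays of each model, at least 2.67-fold higher (n = 3 and 3, adjusted p = 0.095) in Ts65Dn and at least 2.32-fold (adjusted p = 0.53) in Ts1Cje. At 19-20 dpp it was detected on 3 of 3 Ts65Dn, 1 of 3 WT and 0 of 3 Ts1Cje arrays. Ts65Dn lay above WT by 1.48 ± 0.45 (log2, SE, adjusted p = 0.063) and above Ts1Cje at least 2.46-fold (adjusted p = 0.025). Of the probes that changed between Ts65Dn and WT at 19-20 dpp, the named gene Zbtb14 on chromosome 17 was among the 8 that did not move against the age change of Ts1Cje, at −0.74, and it was singled out after its value was seen.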
